A study of Caenorhabditis elegans with 2 samples.

How the data were processed

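Chromatin of whole young adult C. elegans (strain OP214, unc-119(ed3) with the transgene wgIs214) was immunoprecipitated with an antibody against GFP, after sonication, and sequenced. Animals were synchronised by starvation at the first larval stage after bleaching, per the labels. The labels give 2 biological replicates of 1 group, numbered 2 and 3, and no second group, so no difference between conditions was tested. Both are described as biological replicates; nothing says on which days they were made.

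The authors deposited 4 peak lists on build ce11, per the file headers. Peaks of each replicate were called on that replicate's alignments against 1 control alignment, the pooled list was called on both replicates against the same control, and the IDR-thresholded list was derived from these 3 lists. The peak caller, its version, the aligner, filters and the IDR threshold are not given in the sources used here. The deposited signal value of each peak is a score with no stated scaling, and is used only to rank and describe peaks within a list. The deposited significance of each peak is a −log10 q-value, which took at most 3.50 in the IDR list. The control alignment was not used here. All 2268 IDR peaks were found unchanged in the pooled list, and they were its 2268 peaks of highest signal. The relaxed lists reach down to weak peaks: 3659 peaks of replicate 2 and 3601 of replicate 3 had a −log10 q-value above 2 in the deposited files. Most peaks share the caller's standard width within a list, with medians of 510 bp in replicate 2, 384 bp in replicate 3 and 456 bp in the pooled list. In the IDR list 20 entries repeat the interval of another entry, and each entry was counted as a peak. More entries than these had summits close together, some under the same peak of a replicate, and they were also counted singly. Depth is unknown, since a peak list holds no read totals. Intervals given for shares therefore cover counting error over peaks or genes only.

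Genes came from Ensembl release 115 for assembly WBcel235, which is ce11, with 46890 genes on the 6 nuclear chromosomes, 19973 of them protein-coding; all peak ends lay within these chromosomes. A gene had a promoter peak if a summit lay from 1000 bp upstream to 200 bp downstream of its annotated 5' end. For each summit 1 class was assigned, so a summit in a tRNA gene inside an intron counts as tRNA. Shares of summits were compared with 1000 circular shifts of the summits along each chromosome, by a two-sided permutation p. Coding lists were drawn up by patterns in gene names, so any of them can hold genes of other function. Gene lists were compared with all other coding genes, and non-coding classes with all other genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 38 lists of at least 5 members. Odds ratios add 0.5 to each cell so that lists with 0 peaks have a value. For a count of 0 the limit given is 3 divided by the number of genes, which is lower than the upper end of the exact two-sided 95% interval drawn in the figure. As a second test the ratio of the share in the list to that in other genes was compared with its value over 1000 shifts of the summits. Chromosomes were compared with their share of length by two-sided exact binomial tests, adjusted over 6 chromosomes. For 6-mers, with reverse complements merged, the number of windows holding each was compared by Fisher's exact test with adjustment over 2080 sequences. Loci were compared with 1000 random windows of the same width on the same chromosome. Replicates were compared at equal rank, the 2268 strongest peaks of each, because the relaxed lists differ in length. A summit counted as covered if a peak of the replicate lay over it.

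The gene lists, windows, tests and alternatives were fixed before the data were examined, except the statistic of the shifting test and the additions named below. So was the rule for named genes: the coding gene with the 5' end nearest to each of the 25 strongest IDR peaks, the 4 members with the strongest promoter peak in each list past the adjusted threshold of 0.05 for Fisher's exact p (fewer if fewer had one), K12H6.12 and unc-119, and the 3 most enriched 6-mers by odds ratio found in at least 5% of summit windows. Alternatives were each replicate alone, the 1134 IDR peaks of highest signal, other windows and overlaps, clustered genes counted once, and permutation by shifting. Another 5 were chosen after seeing the data: shifting list membership along the gene order, expectations from coding genes for chromosomes and for chromosome centres, non-coding classes against other genes without 21U-RNA genes, and a second statistic for the shifting test. That test was first run with a log odds ratio with 0.5 added to each cell. It was replaced by the ratio of shares after its outcome had been seen, because it made small lists with 0 peaks extreme; both outcomes are given.

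The tests were tried on simulated data. In 20 simulations over 19973 coding genes, lists given an odds ratio of 4 were called in 60 of 60 tests, those given 0.1 in 59 of 60, and those given 1 in 0 of 60. The largest coding lists were used there, and each gene drew its peak independently. Small lists, such as V-ATPase with 21 genes, and genes that share a peak were therefore not tried. The shifting test gave p below 0.05 for 0 of 100 random lists, where 5 would be the nominal number, so it is conservative. For random lists of 6 genes without a peak it gave p below 0.05 in 0 of 20 tests, and the log odds ratio used first did so in 20 of 20. The 6-mer test called 0 of 2080 sequences without a planted one, and ranked a sequence planted in 10% of windows at 1. Both sets of windows were drawn at random from the genome there. The test was therefore not tried with the difference in base composition found between summits and flanks. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.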

Results

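The data came from chromatin immunoprecipitation followed by sequencing in whole young adult Caenorhabditis elegans of 72 hours, of mixed sex, that carried a transgene encoding K12H6.12 with a C-terminal GFP tag. An antibody against GFP was used to pull down chromatin bound by the tagged protein. Both samples carried the tag and the control was not used here. Whether each peak marks a site bound by K12H6.12 was therefore not tested. The labels give 1 group with 2 biological replicates, numbered 2 and 3, so the only comparison of samples was between these replicates. The deposited lists held 27073 peaks for replicate 2, 30000 for replicate 3 and 30000 for both replicates pooled, all called at a relaxed threshold. Another list, thresholded by reproducibility between replicates (irreproducible discovery rate, IDR), held 2268 peaks, which were the 2268 of highest signal in the pooled list. Peak lists carry no read totals, so the depth of each library is unknown. Signal values below are those of the authors' peak caller, in the pooled list unless a replicate is named, and positions are on build ce11.

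The highest signal, 1112, was at chromosome III, 3867356 to 3867785, with its summit in intergenic sequence 276 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its signal was 538 in replicate 2 and 578 in replicate 3. The next peaks stood 61 bp upstream of tasp-1 (signal 1037, summit at III 10759246) and 4766 bp upstream of cmd-1, the calmodulin gene (signal 998, summit at V 1151505). Of the 25 strongest peaks, 19 had the summit inside the promoter window of the nearest coding gene, defined as 1000 bp upstream to 200 bp downstream of the annotated 5' end. These included rpl-15 (signal 768), the histone gene his-37 (730), cdc-48.1 (691), cbp-1, which encodes a histone acetyltransferase (677), iff-2, a translation factor gene (624), puf-9 (614) and rpl-35 (598). Others with a summit within 1000 bp upstream were tag-340, Y39B6A.43, Y17G9B.5, Y39E4B.6, sor-1, epn-1, serp-1.1, tos-1, hsr-9 and W06H8.6. The remaining 6 lay over 2000 bp from the nearest coding 5' end. They were those of cmd-1, R11F4.1, sup-26 and cest-16, and a pair of summits (I 9382988 and 9383196) of the same interval inside ppfr-1. This pair overlapped an annotated non-coding RNA gene, as did the summits of cmd-1, tag-340, epn-1, puf-9 and W06H8.6. The median signal was 676 for these 25 peaks and 147 for all 2268. In both replicates, 24 of the 25 were covered by a peak ranked within the top 100, and the exception, the ppfr-1 summit at 9382988, had no replicate 3 peak over it.

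Taking the 2268 strongest peaks of each replicate, 82.1% of IDR summits were covered in replicate 2 (95% Wilson interval 80.5 to 83.6), 80.6% in replicate 3 (79.0 to 82.2) and 65.9% in both (63.9 to 67.8). Lists shifted along the chromosomes covered 0.0075% in both on average over 100 shifts. The IDR peaks were those of highest signal in a list called on both replicates together, so these shares are high in part by construction. Without that selection, 1546 of the 2268 strongest peaks of replicate 2 (68.2%) had their summit covered by the 2268 strongest of replicate 3, and 1495 (65.9%) the other way round. With the full relaxed lists 97.8% of IDR summits were covered in both replicates, leaving 50 that were not. The signal at 2218 IDR peaks correlated between replicates with a Spearman rho of 0.553 (bootstrap 95% interval 0.520 to 0.585). These peaks are not independent, and the IDR peaks were those of highest signal in the pooled list. The median ratio of replicate 2 to replicate 3 was 1.18, the SD of the log2 ratio was 0.62, and 197 peaks (8.88%) lay over 2-fold from that median.

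**Figure D1:**
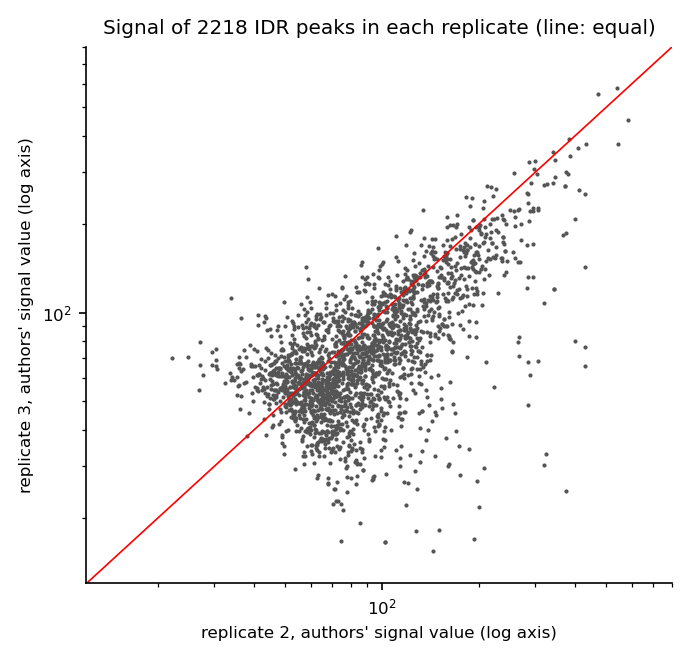
Authors' signal value of 2218 IDR peaks in replicate 2 (horizontal, log axis) and replicate 3 (vertical, log axis), 1 point per peak, with a line at equal values. The rho across peaks is 0.553, and the points spread around a median ratio of 1.18.

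Protein-coding promoters held 1128 of the 2268 IDR summits, 49.7% (95% Wilson interval 47.7 to 51.8). Summits shifted along their chromosomes fell there in 21.05% of cases on average and in at most 24.3% over 1000 shifts, so the share was 2.36 times the shifted mean (two-sided permutation p = 0.002, the smallest these shifts can give). Of the 1232 summits within 1000 bp of the nearest coding 5' end, 82.6% were upstream of it. Intergenic sequence held 58.6% of summits against 33.2% after shifting, and 5' UTRs held 3.70% against 1.41%. Coding exons held 2.16% against 24.4%, introns 19.8% against 33.2%, 3' UTRs 0.705% against 3.35%, and pseudogenes 0.265% against 2.72%. Summits inside tRNA genes made up 3.92% of the total (89 summits) against 0.0501% after shifting, and those inside other non-coding RNA genes 10.8% against 1.71%. For each of these 8 classes the permutation p was 0.002, again the smallest possible. The excess in promoters depended on the window, with 38.5% of summits against 11.01% after shifting for 500 bp upstream to 100 bp downstream, and 62.6% against 39.2% for 2000 bp upstream to 500 bp downstream.

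**Figure D2:**
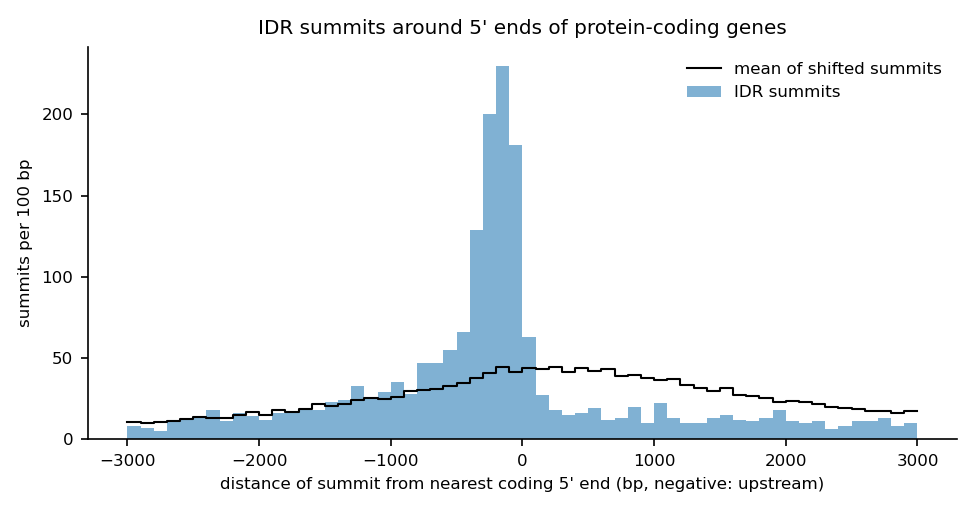
Number of IDR summits per 100 bp (bars) by distance from the nearest protein-coding 5' end in bp, negative values upstream, with the mean of 20 shifted sets as a line. The highest bar, 230 summits, covers the 100 bp that start 200 bp upstream, where the shifted mean is 44.5.

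Genes for the protein synthesis machinery had promoter peaks more often than other coding genes. Of all 19973 coding genes 1418 (7.10%) had one. Among cytosolic ribosomal proteins 47 of 81 genes had a promoter peak, 58.0% against 6.89% of other coding genes (exact 95% interval 46.5 to 68.9; odds ratio 18.6, adjusted Fisher's exact p = 2.68e-32). The strongest were at rpl-3, rpl-15, rpl-20 (676) and rps-19 (612). The rpl-20 peak was also the one nearest to Y17G9B.5, and the rps-19 peak the one nearest to hsr-9. Translation initiation and elongation genes had peaks at 17 of 71 (23.9%, odds ratio 4.24, adjusted exact p = 2.43e-05), led by iff-2, eef-1A.2 (477), eef-1A.1 (332) and eif-3.C (270). The list also takes in aminoacyl-tRNA synthetase genes, of which aars-1, ears-2, kars-1 and mars-1 had a peak. By shifting the summits its adjusted permutation p was 0.0483, close to the threshold. Splicing factor genes had them at 18 of 64 (28.1%; odds ratio 5.26, adjusted exact p = 1.24e-06), led by prp-19 (317), snr-4 (276), snr-1 (255) and snrp-40.1 (248).

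Protein folding and mitochondrial genes were also over-represented. Heat shock and chaperone genes had promoter peaks at 23 of 68 (33.8%; odds ratio 6.85, adjusted Fisher's exact p = 7.23e-10). The strongest were at hsp-1 (556), which encodes a constitutive Hsp70, at hsp-3 (474), whose product is an Hsp70 of the endoplasmic reticulum, at the mitochondrial chaperonin gene hsp-60 (414), and at dnj-13 (372). Nuclear-encoded genes of the respiratory chain had peaks at 20 of 71 (28.2%; odds ratio 5.27, adjusted exact p = 3.42e-07), led by cox-5B (494), cox-5A (472), atp-1 (313) and nduf-2.2 (258).

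A further 6 coding lists passed Fisher's exact test with higher shares but not the permutation test that shifts the summits along the chromosomes; both p-values are adjusted over the lists. Cell cycle and kinetochore genes had peaks at 17 of 79 (21.5%, adjusted exact p = 0.000100, permutation p = 0.0949), led by cdc-48.1, the retinoblastoma-family gene lin-35 (354), mcm-10 (261) and cdk-7 (260). Neuron genes had them at 14 of 66 (21.2%, adjusted exact p = 0.000531, permutation p = 0.179), with unc-76 (280), syd-2 (272), rgef-1 (187) and unc-14 (185) the strongest. Autophagy genes had them at 8 of 28 (28.6%, adjusted exact p = 0.00148, permutation p = 0.175), with epg-7 (367), atg-9 (200), lgg-1 (199) and lgg-2 (180.0) the strongest. Muscle genes had them at 9 of 42 (21.4%, adjusted exact p = 0.00536, permutation p = 0.182), led by unc-112 (245), act-4 (142), unc-60 (139) and unc-89. Proteasome genes had them at 7 of 33 (21.2%, adjusted exact p = 0.0158, permutation p = 0.268), led by rpn-3 (220.5), rpn-11 (176), rpn-9 (142) and pbs-1 (118). V-ATPase genes had them at 5 of 21 (23.8%, adjusted exact p = 0.0253, permutation p = 0.387), led by vha-8 (242), vha-12 (180.3), vha-13 (178) and vha-1 (169.9). Shifting list membership along the gene order, chosen after seeing the data, kept 5 of these 6 lists and not V-ATPase (adjusted permutation p = 0.0615). The statistic first used for shifting the summits kept the cell cycle list. The muscle call was lost without replicate 3 (odds ratio 2.36, adjusted exact p = 0.119), and its odds ratio turned below 1 among the 1134 strongest peaks (0.905). The proteasome call was lost without replicate 2 (2.64, adjusted exact p = 0.113). Stratifying by codon adaptation, a stand-in for transcription level, ended the calls for muscle (odds ratio 1.80), proteasome (1.69) and V-ATPase (1.99).

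Promoter peaks were fewer than at other coding genes in 7 coding lists by Fisher's exact test, and in 3 of them also by shifting. Chemoreceptor genes had them at 6 of 1316 (0.456%; odds ratio 0.0606, adjusted Fisher's exact p = 8.53e-34), with sri-5 (243), sre-23 (184), srh-16 (145) and srh-269 (118) the strongest. The srh-269 summit lay inside a tRNA gene. F-box and MATH-BTB genes had them at 7 of 432 (1.62%, adjusted exact p = 1.00e-06), led by fbxb-85 (230.2), bath-42 (189), fbxb-72 (152) and fbxa-90 (135). C-type lectins had 1 of 240 (0.417%, adjusted exact p = 2.80e-06), at clec-126. These 3 lists also passed the permutation test by shifting, at adjusted p = 0.00949, 0.0228 and 0.0228. Another 4 passed Fisher's exact test but not this shifting of the summits. Shifting list membership along the gene order, a test chosen after seeing the data, kept 3 of these 4 and not the collagens (adjusted permutation p = 0.0569), and the statistic first used for shifting the summits kept neuropeptide and cytochrome P450 genes. Neuropeptide genes had 0 of 102, which allows a share of up to 2.94% (adjusted exact p = 0.00340, permutation p = 0.268). Cytochrome P450 genes had 0 of 74, which allows up to 4.05% (adjusted exact p = 0.0188, permutation p = 0.581). Collagens had 5 of 174 (2.87%, adjusted exact p = 0.0417, permutation p = 0.319), the strongest at col-38, col-71, col-42 and col-185. The list of lysozymes, saposins and infection response genes had 1 of 126 (0.794%, adjusted exact p = 0.00536, permutation p = 0.268), and that member, ift-81, is known for intraflagellar transport in cilia rather than for infection response; without replicate 3 this call was lost (adjusted exact p = 0.0609).

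Small RNA genes were marked unevenly. Peaks lay in the promoter window of 191 of 612 tRNA genes (31.2%, exact 95% interval 27.6 to 35.05) against 5.19% of all other annotated genes, an odds ratio of 8.29 (adjusted Fisher's exact p = 1.28e-88). Among the 23 of them with at least 90% of 31-mers unique in the genome the share was 8.70% (1.07 to 28.0), so reads shared between copies are not excluded. The strongest were at WBGene00014567, WBGene00022947, WBGene00023221 and WBGene00023042, with signals of 365, 357, 356 and 306. At WBGene00014567 no replicate 3 peak lay over the summit, and the WBGene00023221 summit lay 913 bp upstream, in an intron. Genes for snoRNAs, which guide modification of ribosomal RNA, had peaks at 105 of 346 (30.3%; odds ratio 7.73, adjusted exact p = 2.82e-47). The strongest were at K11H12.12 and K11H12.13, which share the rpl-15 peak, at C06A1.9, which shares that of cdc-48.1, and at F54C9.12, which shares that of iff-2. Genes for 21U-RNAs, the germline piRNAs, had them at 169 of 15363 (1.10%; odds ratio 0.134, adjusted exact p = 3.97e-239), with 21ur-13751, 21ur-13616, 21ur-3187 and 21ur-8481 the strongest. With clustered members counted once, 56 of 1248 clusters had a peak (adjusted exact p = 3.50e-05). These 3 classes kept their calls when the summits were shifted (permutation test, adjusted p = 0.00949, from the smallest p the shifts can give). The group of all other genes includes the 21U-RNA genes, which lowers its share. Against other genes without them, a comparison chosen after seeing the data, the odds ratio was 5.83 for tRNA genes and 5.43 for snoRNA genes, and the calls for microRNA genes (adjusted exact p = 0.330) and for snRNA and spliced leader genes (adjusted exact p = 0.267) were lost. MicroRNA genes had peaks at 25 of 261 (9.58%, against all other genes adjusted exact p = 0.0179, permutation p = 0.362). A single peak (signal 340.0) served cel-mir-54, cel-mir-55 and cel-mir-56, and cel-mir-5549 shared the eef-1A.1 peak. The snRNA and spliced leader genes had peaks at 14 members (10.9%, adjusted exact p = 0.0306, permutation p = 0.268), with sls-2.1 (534), sls-2.4 (513), sls-2.2 (504) and R07E5.16 (393) the strongest, and this call was lost without replicate 3 (adjusted exact p = 0.333).

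In all, 23 of 38 gene lists passed Fisher's exact test, 15 higher and 8 lower. The other 15 did not: UDP-glucuronosyltransferases (1 of 67), P granule and germline small RNA (4 of 30), homeobox (3 of 96), major sperm proteins (0 of 31, which allows up to 9.68%), nuclear hormone receptors (14 of 274), glutathione S-transferases (1 of 49), long non-coding RNA (20 of 294), core histones (7 of 72), hypodermis and hedgehog-related (2 of 59), fatty acid metabolism (6 of 76), pharynx (7 of 86, all 7 of them pqn genes, which are named for domains rich in glutamine and asparagine and not for the pharynx), oocyte and eggshell (1 of 32), intestine markers (2 of 46), meiotic chromosome axis and synapsis (2 of 33) and vitellogenins (0 of 6). Their adjusted p ranged from 0.143 to 1. Genes in 1 cluster can share a peak, so Fisher's exact test counts some peaks more than once; by shifting the summits, 11 of the 23 calls held. Calls were also lost for cell cycle, proteasome, muscle, neuropeptide and cytochrome P450 genes among the 1134 strongest peaks, for cytochrome P450 with the narrower promoter window, and for collagens and microRNAs when clustered genes were counted once. Calls were gained for nuclear hormone receptors without replicate 3, long non-coding RNAs among the 1134 strongest peaks and UDP-glucuronosyltransferases with the wider promoter window.

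**Figure D3:**
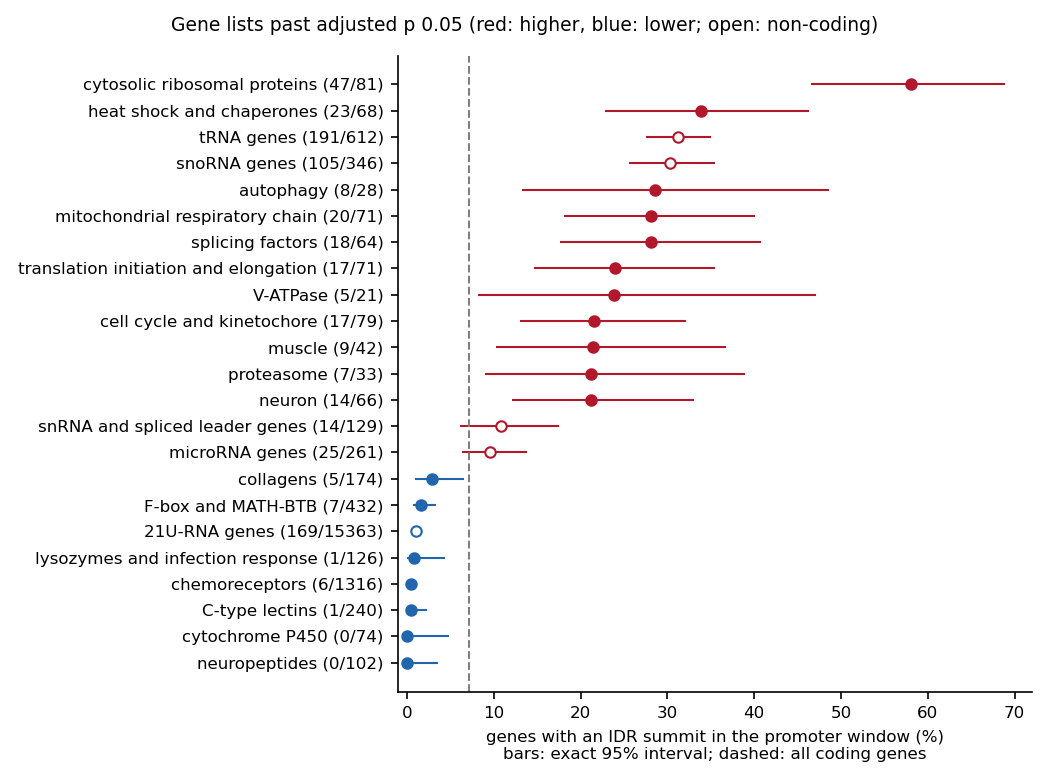
Share of genes with an IDR summit in the promoter window, in percent, for the 23 gene lists past adjusted exact p = 0.05 by Fisher's exact test, with exact 95% intervals as bars and the share of all coding genes, 7.10%, as a dashed line. Ribosomal proteins stand highest at 58.0%, and neuropeptides and cytochrome P450 genes at 0.

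Chromosome X carried 486 IDR peaks, 27.4 per Mb and 1.21 times the number given by its length (95% interval 1.12 to 1.31; exact binomial test, adjusted exact p = 1.43e-05). Chromosomes III (1.24 times, adjusted exact p = 2.20e-05) and I (1.16 times, adjusted exact p = 0.00180) were also above their share. Chromosome V was below it with 338 peaks, 0.714 times (0.645 to 0.788, adjusted exact p = 2.46e-12), as was chromosome IV (0.842 times, adjusted exact p = 0.000658). Chromosome II did not differ by this measure (0.952 times, 0.858 to 1.05, adjusted exact p = 0.350), but fell below its share of coding genes (0.840 times, adjusted exact p = 0.000499). By that comparison, chosen after seeing the data, X stood highest at 1.57 times, before III (1.29) and I (1.21), with V at 0.596 and IV at 0.894. Summits within 100 bp of a tRNA gene, also counted after seeing the data, made up 77 of the 486 on X. They made up 79 of the 1782 on the autosomes, and the chromosome tests were not repeated without them. On the autosomes 1112 of 1782 peaks, 62.4% (60.1 to 64.7), lay in the middle 50% of chromosome length, where gene density is higher and repeats are fewer (exact binomial p = 8.56e-26). Against the 55.7% of autosomal coding genes found there, also chosen after seeing the data, the excess was 1.12-fold (exact p = 8.71e-09). The binomial tests treated close summits as independent, so their p-values can be too small and their intervals too narrow.

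Sequences rich in G and C marked the summits, and so did repeats of GA. The most enriched 6-mers within 50 bp of a summit were AGCGCG, in 8.86% of summit windows against 1.19% of windows 300 bp away (odds ratio 8.02, adjusted Fisher's exact p = 2.49e-50), ACGCAG, in 16.8% against 2.51% (7.81, adjusted exact p = 9.60e-93), and GCGCGC, in 7.14% against 0.992% (7.62, adjusted exact p = 1.07e-39). This ranking was by odds ratio. Lower odds ratios but larger shares were found for GAGAGA, in 30.4% against 7.32% (5.53, adjusted exact p = 3.14e-128). The same held for AGAGAG, in 25.3% against 5.78% (5.52, adjusted exact p = 2.89e-108). Of 2080 6-mers, 701 were enriched and 486 depleted at adjusted p below 0.01. The enriched ones held a mean of 4.03 G or C bases and the depleted ones 1.56. Among depleted 6-mers found in at least 5% of flanking windows, TAATTA had the lowest odds ratio, in 0.882% of summit windows against 5.38% (0.160). G and C made up 48.3% of bases in summit windows, 35.7% in the flanks and 35.4% in the genome, so the flanks did not match the base composition of the summits.

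No peak of any list lay within 20 kb of K12H6.12, the tagged gene at chromosome II, 2808156 to 2812860. Random windows of that width on chromosome II held a mean of 12.03 relaxed peaks in replicate 2 (two-sided permutation p = 0.020), 13.8 in replicate 3 (p = 0.00799) and 13.8 in the pooled list (p = 0.032). They held 0.935 IDR peaks on average, so a count of 0 there was common (permutation p = 1). With 10 kb to either side the counts were also 0 and no permutation p was below 0.0759, and with 40 kb they were 8, 17 and 13 against random means of 23.1, 26.4 and 26.2 (p = 0.12, 0.39 and 0.24). The gene sat in a stretch of 57.1 kb without a peak in the pooled list, the 41st longest of 30006 such stretches, whose median was 1546 bp. Around unc-119, the gene mutated in this strain, there were 2 IDR peaks within 20 kb against a random mean of 1.32 (permutation p = 0.701). Both lay in introns of unc-119 (summits at III 10903288 and 10905346), each with a signal of 105, and the 2268 strongest peaks of each replicate held 1 there, but not the same one: near the first summit in replicate 2 (signal 85.6) and near the second in replicate 3 (52.1).

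**Figure D4:**
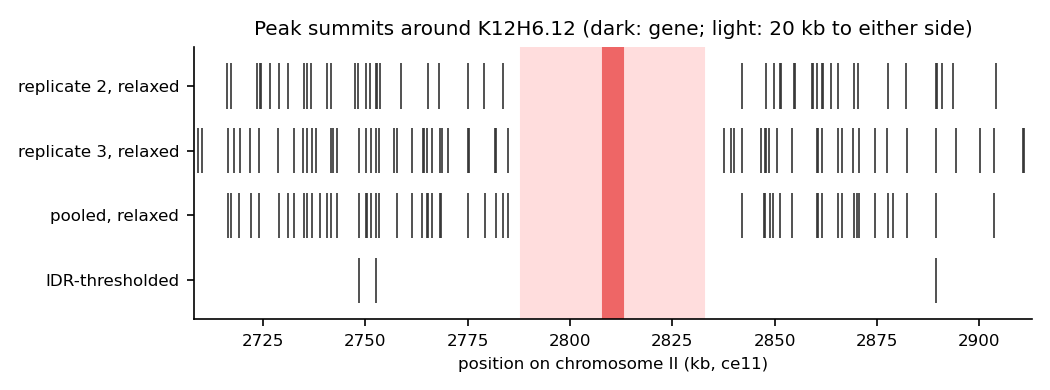
Peak summits (vertical lines) around K12H6.12 on chromosome II, in kb on build ce11, for the 4 lists. The gene is shaded dark and the 20 kb to either side light, and no summit of any list falls in the shaded part.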

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

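Shifting list membership along the gene order, expectations from coding genes, non-coding classes against genes other than 21U-RNA genes, and the ratio of shares as the statistic of the shifting test were chosen only after the results were seen. Permutation by shifting the summits left 7 lists higher and 4 lower, against 15 and 8 by Fisher's exact test; this test is conservative on random lists. With the log odds ratio used first, the same shifts left 9 and 7, among them the major sperm proteins and vitellogenins, which have 0 peaks; that statistic was replaced after this outcome was seen because it called 20 of 20 random lists of 6 genes without a peak. Shifting membership along the gene order left 12 and 7. Without 21U-RNA genes in the comparison 13 and 8 remained, with microRNA and snRNA and spliced leader genes lost. Leaving out 1 replicate gave 13 to 14 lists higher and 8 lower. The muscle list reversed to an odds ratio of 0.905 among the 1134 strongest peaks, and the cause was not tested. Summits covered by both replicates were 61.6% when summits had to lie within 100 bp, 68.3% with an overlap of 50% of the shorter peak and 97.8% with the full lists; longer lists cover more by construction. The ratio for promoters was 2.25 to 2.41 without 1 replicate, that for chromosome centres 1.24 to 1.28, and the number of chromosomes past the test 5. Enriched 6-mers numbered 593 to 713 and depleted ones 441 to 506 without 1 replicate. Among the 2268 strongest peaks of 1 replicate, 0 lay within 20 kb of K12H6.12 and 1 within 20 kb of unc-119, a different peak in each replicate. Over all alternatives, 374 of the values for single lists stayed on their side of the threshold and 5 gained a call. Another 39 lost a call, 1 of them with a reversed direction. Direction was compared only where a list was called with at least 1 of the settings compared. Long non-coding RNA genes, without a call, changed direction against genes other than 21U-RNA genes (odds ratio 1.28 before, 0.895 after). Peaks with the best IDR score alone were not tested, because the score is 0 for every peak. No paired analysis was possible because there is only 1 group. Unknown depth limits any statement on peaks missing from a list.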

Other observations

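Tests on the stretch without peaks around K12H6.12 by its surroundings, on codon adaptation for the muscle, proteasome and V-ATPase lists, and the values for spliced leader genes, chromosome X and a longer sequence were chosen only after the results were seen. Genes for the SL2 spliced leader, sls-2, which is joined to downstream genes of operons, had promoter peaks at 5 of 18, whereas the SL1 genes, sls-1, had 0 of 12, which allows a share of up to 25%. This difference did not pass Fisher's exact test (p = 0.0657), and no 31-mer of the sls-1 genes, which lie on chromosome V, was unique in the genome (0%), against 72.4% in sls-2. On chromosome X 39.1% of 486 summits lay in coding promoters, against 52.6% of 1782 on the autosomes (Fisher's exact p = 1.26e-07). X holds 17.7% of the genome length but 13.7% of the coding genes, so it has fewer coding promoters for its length. These shares were not compared with shifted summits by chromosome, so a trait of X beyond gene density was not tested. Summits within 100 bp of a tRNA gene made up 15.8% of those on X and 4.43% of those on the autosomes (exact p = 1.33e-15), and X carries 276 of the 612 annotated tRNA genes.

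Overlapping 6-mers among the 10 most enriched joined into GAGACGCAGA, which was present in 7.01% of summit windows (159) and 0.419% of flanking windows. It was found at 0 of 156 summits within 100 bp of a tRNA gene and at 7.53% of the other 2112 (Fisher's exact p = 1.25e-05). Since this sequence was assembled from these windows, its share at summits is not independent evidence.

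Promoter peaks at the 11 coding lists with higher shares were set against base composition and transcription. The share of coding genes with a peak rose from 1.35% in the lowest decile of promoter GC content to 15.6% in the highest, and from 1.55% to 15.1% over deciles of codon adaptation to ribosomal protein genes. After stratifying by GC content 11 of 11 lists stayed past the adjusted threshold, with a median odds ratio of 4.02 against 4.37 before. This argues against the mean GC content of the promoter window as the whole cause. GC content close to summits, 48.3% within 50 bp against 35.7% in the flanks, was not stratified for, so its part stays open. After stratifying by codon adaptation, used as a stand-in for transcription level, 7 of the 10 lists other than ribosomal proteins stayed, with a median over the 11 of 2.79 and smaller odds ratios for ribosomal proteins (18.6 before, 9.05 after), the respiratory chain (5.27, 2.65) and translation genes (4.24, 2.53). For muscle (3.73 before, 1.80 after), proteasome (3.72, 1.69) and V-ATPase (4.37, 1.99) the call ended with the smaller odds ratio in small lists, and whether transcription level accounts for these peaks cannot be told apart; no other biological explanation was tested.

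Peaks at tRNA and snoRNA genes could come from coding promoters nearby. Among genes with no coding 5' end within 1 kb, 28.8% of 427 tRNA genes (exact 95% interval 24.6 to 33.4) and 21.3% of 211 snoRNA genes (16.002 to 27.5) still had a peak. These shares were above the 7.10% of coding genes, which argues against coding 5' ends within 1 kb as the whole cause. The share was higher with such a 5' end, at 36.8% and 44.4%. Promoter windows reach 1000 bp upstream, so a coding gene with its 5' end farther than 1 kb away can share a summit. Only 1 annotated 5' end per gene was used. Coding promoters beyond 1 kb and other transcript starts are therefore not excluded. Reads shared between near-identical tRNA genes stay open: of the 23 tRNA genes with at least 90% of 31-mers unique in the genome, 2 had a peak, or 8.70% (1.07 to 28.0), against 32.1% (28.3 to 36.03) of the 589 others, which goes with shared reads, but the 23 are too few to exclude a share above that of coding genes. No biological explanation was tested.

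The absence of relaxed peaks around K12H6.12 might reflect repeated sequence or a stretch poor in peaks. Its window had 99.5% unique 31-mers, at percentile 91.5 of windows of that width on chromosome II, which argues against repeated sequence. Of 1911 such windows within 1 Mb 0% lacked a peak in all 3 relaxed lists, but these overlap, only 44 fit side by side (upper exact limit 8.04%, above the bound of 5%), and they held a median of 8 pooled peaks against 14 on all of chromosome II, so a stretch poor in peaks stays open, although the 8 empty windows among 15235 on the whole chromosome all overlapped the K12H6.12 window. Extra copies of this region from the transgene in the control, or filtering by the authors, stay open, since neither the control nor the filters were used here. No biological explanation was tested.

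The scarcity of peaks at 21U-RNA genes might follow from few peaks of any kind in the regions of chromosome IV that hold most of them. In the 7 bins of up to 1 Mb (the last ends with the chromosome) with over 500 21U-RNA genes each, 5.22% of 1015 coding genes had a promoter peak (exact 95% interval 3.94 to 6.77), against 7.20% of other coding genes and 0.984% of the 21U-RNA genes in those bins. The last share counts clustered 21U-RNA genes singly. Counted once per cluster over all chromosomes, 56 of 1248 clusters had a peak. The share of coding genes stayed above 50% of the share elsewhere, the bound set in advance. This argues against few peaks in these bins as the whole cause of the gap to other genes. Coding promoters held 2.36 times the share of summits found after shifting. Whether 21U-RNA genes have fewer peaks than positions outside promoters was not tested. The bins may still add to the gap, since they held 16.02 IDR peaks per Mb against 22.6 in the genome, and 2.42% of 21U-RNA genes outside them had a peak (1.64 to 3.43).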
